A study of Mus musculus with 6 samples.

How the data were processed

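RNA of 6 cultures of mouse fetal liver erythroblasts was hybridized to Illumina MouseWG-6 v2.0 bead arrays, 1 array per culture. Per the labels' protocols, total RNA was amplified and labelled with biotin by a commercial kit. The deposited non-normalized table gives for each probe and array the mean bead intensity, the standard error of the bead intensities, the number of beads and a detection p-value. Per the file headers, these intensities were exported with GSGX 1.9.0 at probe level, without normalization and without background subtraction. The detection p-value is the export software's comparison of a probe with the negative control probes, per the file headers. A second deposited table, the series matrix, holds the authors' processed intensities of the same arrays on a linear scale. Its columns followed the raw signal of their own array with a Spearman correlation of at least 0.999993 and of any other array with at most 0.93254, so the match of columns to arrays was checked. About 35% of its values lay below 0 and the column medians were 6.1 or 6.2, the pattern of background-subtracted and quantile-normalized intensities. How the authors made these values is not given in the sources used here, and the series matrix entered only an alternative setting.

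The 6 samples fall into 3 control and 3 Plek2 knockdown cultures by their titles, which also number the replicates 1 to 3 in each group. The design text calls the replicates biological. All sample columns of both tables were mapped through the sample names in the labels. The labels do not settle how long the cells stayed in medium with erythropoietin: the growth protocol gives 12 hours and the design text 24 hours. Slide positions and hybridization batches are not given in the sources used here, so no slide was fitted as a block.

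Signals were processed with limma 3.58.1 (statmod 1.5.0) in R 4.3.3. Background was corrected by normexp with parameters inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2 transformation (neqc). Of the 45281 probes, the 17967 (39.7%) with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept. They carry 12210 gene symbols. The offset compresses differences of dim probes, while the normexp correction enlarges them relative to the uncorrected signal. The fold changes of dim probes therefore depend on both settings. A probe with a detection p-value of 0.05 or more on every array of a group has only a bound there. For such a probe the brighter group's mean was set against the dim group's mean of, per array, the higher of the probe's own level and the lowest level among detected probes, and the result is given as "at least" a fold. Other fold changes are differences of group means on the log2 scale. Means are given with the standard deviation (SD) over the 3 arrays of a group, and log2 fold changes with the standard error (SE) of the fit.

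Gene symbols of the array design were updated through unversioned RefSeq accessions in a gene table of assembly GRCm38.p6. Accessions of 29370 probes matched. For 3267 of the other probes, 1027 of them kept, the design symbol was replaced through a synonym that the same table gives to 1 gene only. Such a name is less certain, above all where the design names a clone. In all 36323 probes carry a current symbol, and 8639 symbols changed. The files name no genome build, so no coordinates are given. Different probes of a gene were tested separately. Where 1 probe had to stand for a gene, in the gene lists, it was the kept probe with the highest mean over all 6 arrays.

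Each probe was tested with lmFit and eBayes on the group alone, with all 6 arrays, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probes kept. An adjusted p under 0.05 was the threshold, without a fold threshold. Gene lists were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists with at least 5 members measured. Beside it, camera with a correlation estimated per list and fry were run. fry tests whether the genes of a list move one way on balance, and its mixed test whether they change in either direction. Neither compares a list with other genes. With an estimated correlation, camera called 0 of the 29 lists, with or without the replicate number as a block. fry with that block also called 0. Their p-values are limited by the few residual degrees of freedom of 6 arrays. A call lost in these tests therefore cannot tell a weak list from a strong one. The 29 lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover the erythroid program (heme synthesis, globins, red cell membrane, late maturation, early progenitor genes, transcription factors, enucleation), the question (Epo and Stat5 targets, intrinsic apoptosis, p53 targets, oxidative stress, cofilin and actin regulators, SRF and MRTF targets), general programs (cell cycle phases, ribosome biogenesis, integrated stress response, immediate early genes, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation), the interferon response as a known side effect of hairpin RNA, and markers of other cell types in fetal liver (macrophage, neutrophil, mast cell with basophil and eosinophil, megakaryocyte, hepatic, lymphoid, endothelial and stromal).

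Named genes are Plek2 and its paralog Plek with every probe. Next come the 12 genes with the largest rises and the 12 with the largest falls among probes past the threshold whose knockdown and control values do not overlap, with 1 probe per gene and without clone-like names after the update. Where fewer than 12 passed in a direction, genes with the smallest unadjusted p in that direction were added and are given as values. Then come up to 4 members of each list with the smallest unadjusted p. A gene outside this rule is named as chosen after its values were seen. Some genes this rule picks are not reported here.

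The replicate numbers were checked as pairs. The deviations from the group means of equally numbered control and knockdown arrays correlated across probes at 0.884, 0.758 and 0.553 for replicates 1, 2 and 3, against at most -0.446, 0.494 and 0.494 with arrays of another number, so replicates 2 and 3 were less clearly told apart. All 3 lie above 0.1, the value fixed beforehand, so the numbers were taken to pair the samples, and the value with the replicate number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times. Arrays of a group were also compared for duplicates. Between 14.2% and 56.9% of the probes kept differed by more than 3 bead standard errors between arrays of a group, so no array of a group was a copy of another. This cannot tell repeated hybridizations of the same RNA from separate cultures. Each array was counted as 1 sample because the design text calls the replicates biological.

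The procedure was tested on simulated data with the 17967 probes, 100 probes changed by 1 and 100 by 2 on the log2 scale. The fit on the group alone recovered 6% of the former and 79% of the latter with 0 false calls among 86. The fit with the replicate block recovered 98% and 100%, with 18 unchanged probes among 252 calls. The simulated pair effects and spread were taken from the block fit, so its better recovery was built in. It does not show which fit suits the real arrays. In the same simulation a downward shift of the heme synthesis list by 1 log2 unit was called and 0 other lists were. This shift was larger than the median of -0.24 in the real data. Members of a list varied independently there, so the simulation cannot show how often correlated lists are called falsely.

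Alternatives covered the background correction, the normalization between arrays, the authors' processed values, the filter on dim probes, the replicate block, the variance model, array weights, 1 probe per gene, the threshold, the list test and each array left out in turn. Leaving out whole replicate pairs, lists without interferon list members, probe symbols without synonyms, and the estimated correlation together with the block were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.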

Results

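Gene expression was profiled in erythroid precursors from the liver of C57BL/6 mouse fetuses at E13.5, when the liver is the main blood-forming organ. The cells lacked TER119, a surface antigen that appears as erythroblasts mature. They received a retrovirus carrying either a control short hairpin RNA (shRNA) or one directed against Plek2, which encodes pleckstrin-2, a membrane- and actin-associated protein. They were then kept 24 hours without erythropoietin (Epo), the cytokine that drives terminal erythroid differentiation, and afterwards with it. Each group held 3 cultures. The median raw signal of the arrays lay between 109.4 and 117.4 intensity units, the median of probes with a detection p over 0.5 between 98.8 and 105.8, and the median of the probes kept between 235.8 and 287.9. Between 17175 and 18310 probes were detected per array, with a median of 42 beads per probe. The precision is limited by the 3 arrays per group.

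The first comparison asked how far the knockdown lowered its target. Plek2 signal was lower on each of the 3 knockdown arrays than on any control array. The probe ILMN_2855998 (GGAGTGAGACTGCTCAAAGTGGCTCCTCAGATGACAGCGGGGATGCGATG) had a log2 signal of 8.43 ± 0.05 (SD, n = 3) in control and 7.31 ± 0.47 (SD, n = 3) in knockdown cultures, which is 45.9% of control. The probe ILMN_2772855 (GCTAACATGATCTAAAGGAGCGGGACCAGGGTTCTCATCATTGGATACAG) stood at 7.95 ± 0.01 and 6.70 ± 0.70, or 42.2% of control. Within pairs of equal replicate number the first probe stood at 43.7%, 66.6% and 33.1% of its control, and the second at 42.4%, 68.7% and 25.9%. Plek, the pleckstrin gene expressed in platelets and leukocytes, was measured at 7.58 ± 0.41 in control and 8.09 ± 0.40 in knockdown cultures. In the fit on the group alone neither Plek2 probe passed the threshold, with a log2 fold change of -1.12 (SE 0.242, limma adjusted p = 0.109) and -1.24 (SE 0.335, adjusted p = 0.231). With the replicate block both passed (adjusted p = 0.0228 and 0.0396), as did the difference of Plek (adjusted p = 0.0269 with the block and 0.746 without), while over the alternatives tried the adjusted p of the first probe ran from 0.00676 to 0.996, and it was 0.0353 without knockdown replicate 2, the culture with the most Plek2 left.

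**Figure D1:**
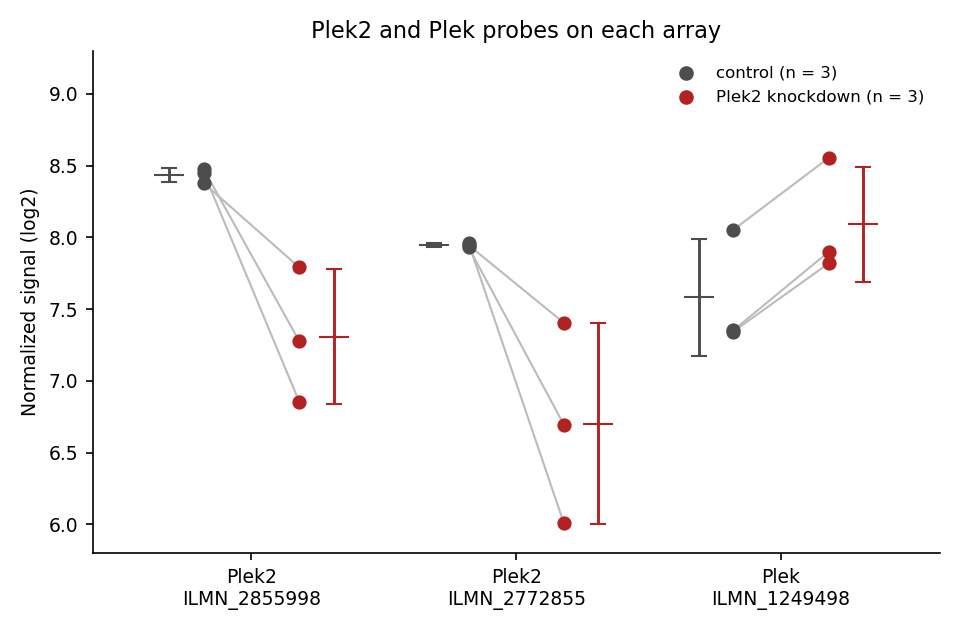
Normalized log2 signal of both Plek2 probes and the Plek probe on each array, control in grey and Plek2 knockdown in red, with lines joining arrays of the same replicate number and bars for mean ± SD (n = 3). Plek2 signal of all 3 knockdown arrays lies below that of the control arrays, with knockdown means of 7.31 and 6.70 against control means of 8.43 and 7.95.

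The second comparison asked which other transcripts differed after the knockdown. In the fit on the group alone 312 of the 318 probes past the threshold were higher. In the simulation this fit recovered few small changes. In all, 908 probes were higher and 392 lower with the replicate block, and 998 and 748 with array weights. Cxcl10, a chemokine that attracts T cells, rose by 6.15 on the log2 scale (SE 0.83, 70.9-fold, limma adjusted p = 0.0168), from 6.92 ± 1.66 to 13.06 ± 0.76 (SD, n = 3). Ifnb1, which encodes interferon beta, was not detected on any control array and was detected on all 3 knockdown arrays, at least 40.9-fold higher in this fit (adjusted p = 0.0132). The chemokines Ccl5 and Ccl7 rose by 4.91 (SE 0.7) and 4.63 (SE 0.463). The remaining genes among the 12 largest rises were Ifi205 at 4.57, Oasl1 at 4.33, Mx2 at 4.27, Usp18 at 4.21, Nlrc5 at 4.07 and Phf11a at 4.01 log2 units, together with Apol9b and Serpina3f, which were not detected in control cultures and were at least 15.5-fold and 13.2-fold higher in this fit. These bounds depend on the background correction: without normexp Ifnb1, Apol9b and Serpina3f stood at 3.58, 2.25 and 2.13 log2 units, below them. The other rises were smaller there too, such as 5.09 for Cxcl10 and 3.69 for Ccl5. Oasl1 and Mx2 are antiviral effectors, Usp18 removes the ubiquitin-like modifier Isg15 from proteins, and Nlrc5 is a transactivator of MHC class I genes.

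Falls past the threshold were found for 5 gene symbols, of which 4 are described. Ednrb, the endothelin receptor type B, fell by 2.44 (SE 0.257, limma adjusted p = 0.00654), and its other probe fell by 1.12 (adjusted p = 0.041). The probe ILMN_1250402, which the array design names after a clone and which is tied to Serbp1 only by a synonym, fell by 1.64 (SE 0.234). The 3 probes of Serbp1, an mRNA-binding protein, with a RefSeq accession stayed short of the threshold, at -0.17 to -0.40, so no fall of this gene is stated. Gmpr, a GMP reductase, fell by 0.81 (SE 0.138), a call lost with median scaling (adjusted p = 0.0749) and cyclic loess (0.0659). Cd300lb, a receptor of myeloid cells, was undetected in knockdown cultures and at least 1.52-fold lower in this fit. Its size depended on the background correction. It stood at -0.22 log2 units without normexp (adjusted p = 0.231) and -0.41 with an offset of 50 (adjusted p = 0.141). The call was lost in both. Genes added as values were Tlcd4 (-1.45), Hs2st1 (-0.89), Reep6 (-0.85), Armc6 (-0.71) and Cbx6 (-0.61), together with Etfbkmt, which was not detected in knockdown cultures and at least 1.44-fold lower in this fit (-0.18 log2 units without normexp). Their adjusted p lay between 0.0588 and 0.103. Each of them passed with the replicate block (adjusted p between 0.00932 and 0.0261).

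In total 318 of 17967 probes passed, 312 higher and 6 lower in the knockdown cultures, representing 236 and 5 gene symbols. All 318 had non-overlapping groups, as had 14.7% of all probes tested, where chance gives 10% for 3 against 3 arrays. The median size of change among the 318 was 3.87-fold. Of 97 called genes with several probes, 6 had probes of opposite sign. The replicate block raised the count to 1300 probes, 908 higher and 392 lower, which included all 318. The count dropped to 190 without control replicate 2, 120 without control replicate 3 and 169 without knockdown replicate 3. Without the filter on dim probes Cxcl10, Ifnb1, Ccl5, Usp18, Serpina3f and the probe ILMN_1250402 were no longer past the threshold (adjusted p between 0.0807 and 0.153). Without normexp the calls of Ifnb1, Ccl5 and Serpina3f were lost (adjusted p = 0.113, 0.081 and 0.113).

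**Figure D2:**
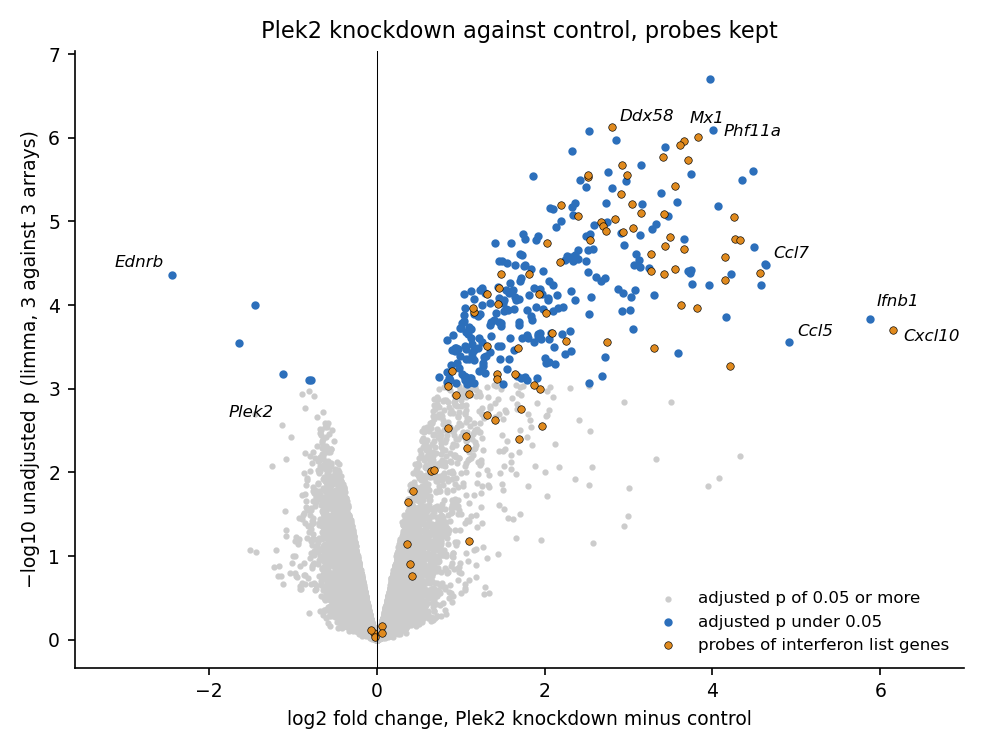
Log2 fold change (knockdown minus control) against -log10 of the unadjusted limma p for the 17967 probes kept, with probes past an adjusted p of 0.05 in blue and all probes of genes on the interferon list in orange with a black edge. Of the 318 probes past the threshold 312 lie to the right of 0, and Cxcl10 lies farthest right at 6.15.

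**Figure D3:**
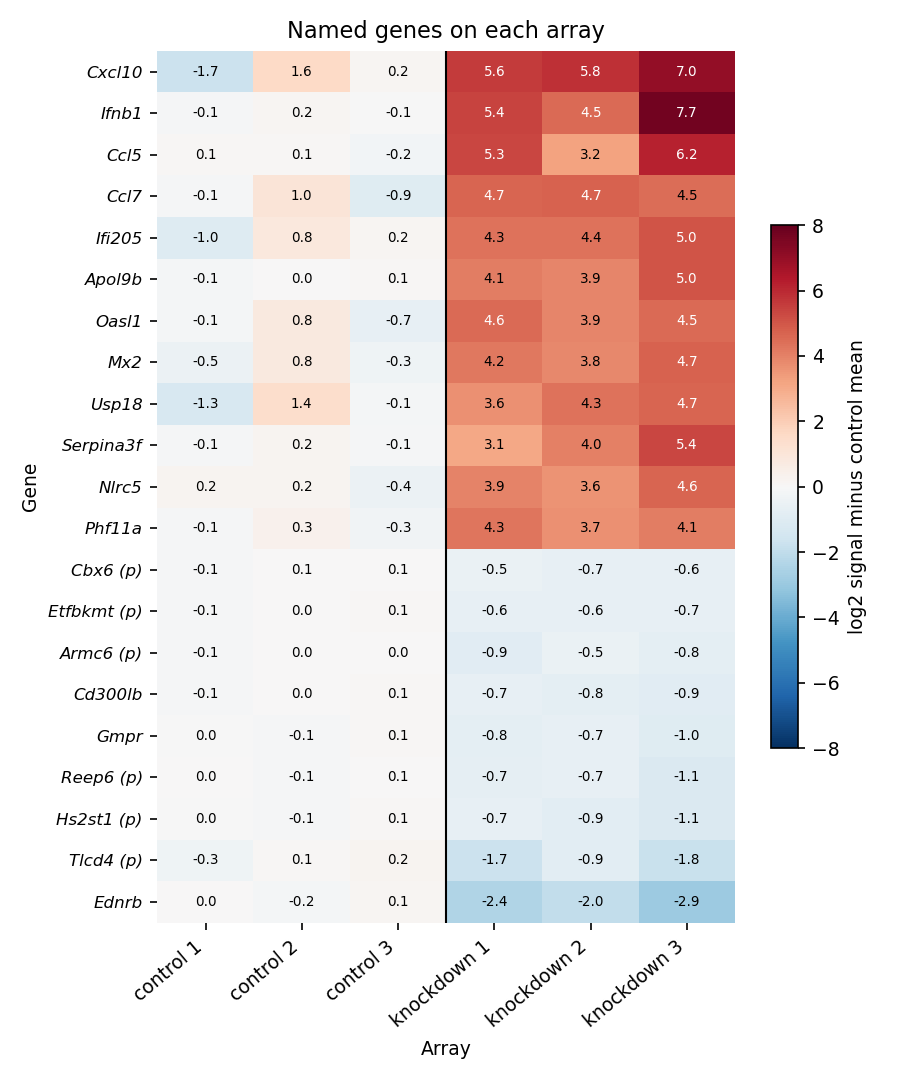
Log2 signal minus the control mean for the 12 largest rises and 9 genes that were lower, 1 column per array; (p) marks genes short of the threshold, given as values. The 12 upper genes exceed every control value on each of the 3 knockdown arrays, and control replicate 2 has the highest control signal of Cxcl10 and Usp18.

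The third comparison took gene lists fixed beforehand. The interferon response list carried the main change. Of 48 members measured, 38 rose, 0 fell and 10 did not pass, and 46 rose when adjusted over the list alone. The median change was 2.53 log2 units (5.77-fold), with medians of 2.72, 2.14 and 2.90 in the replicate pairs, and all 48 differences were positive. The RNA sensor Ddx58 (RIG-I) rose by 2.80 (SE 0.155), Mx1 by 3.83 (SE 0.222), the guanylate-binding protein Gbp2 by 3.66 (SE 0.215) and Irf7, a transcription factor of interferon genes, by 3.71 (SE 0.236), each with a limma adjusted p of 0.00244. The 10 members short of the threshold stood at 0.37 to 1.97 log2 units; B2m, the MHC class I light chain (0.85, adjusted p = 0.0513), is named as an example chosen after its value was seen. The list stood apart from other genes by camera with the preset correlation (adjusted p = 2.29e-84) and moved up on balance by fry (adjusted p = 0.00437). The call was lost at an adjusted p = 0.167 with an estimated correlation, where the members' estimated correlation was 0.402, and by fry with the replicate block (adjusted p = 0.158). Several members, such as Ifi205, Ifit3 and the Oas1 and Gbp genes, belong to families with near-identical copies, and the assignment of their probes to a single copy is uncertain. The RNA came from whole cultures, so the rise cannot be assigned to a single cell type. Neutrophil and myeloid granule markers had a median control level of 12.39 on the log2 scale, against 10.7 for heme synthesis genes.

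**Figure D4:**
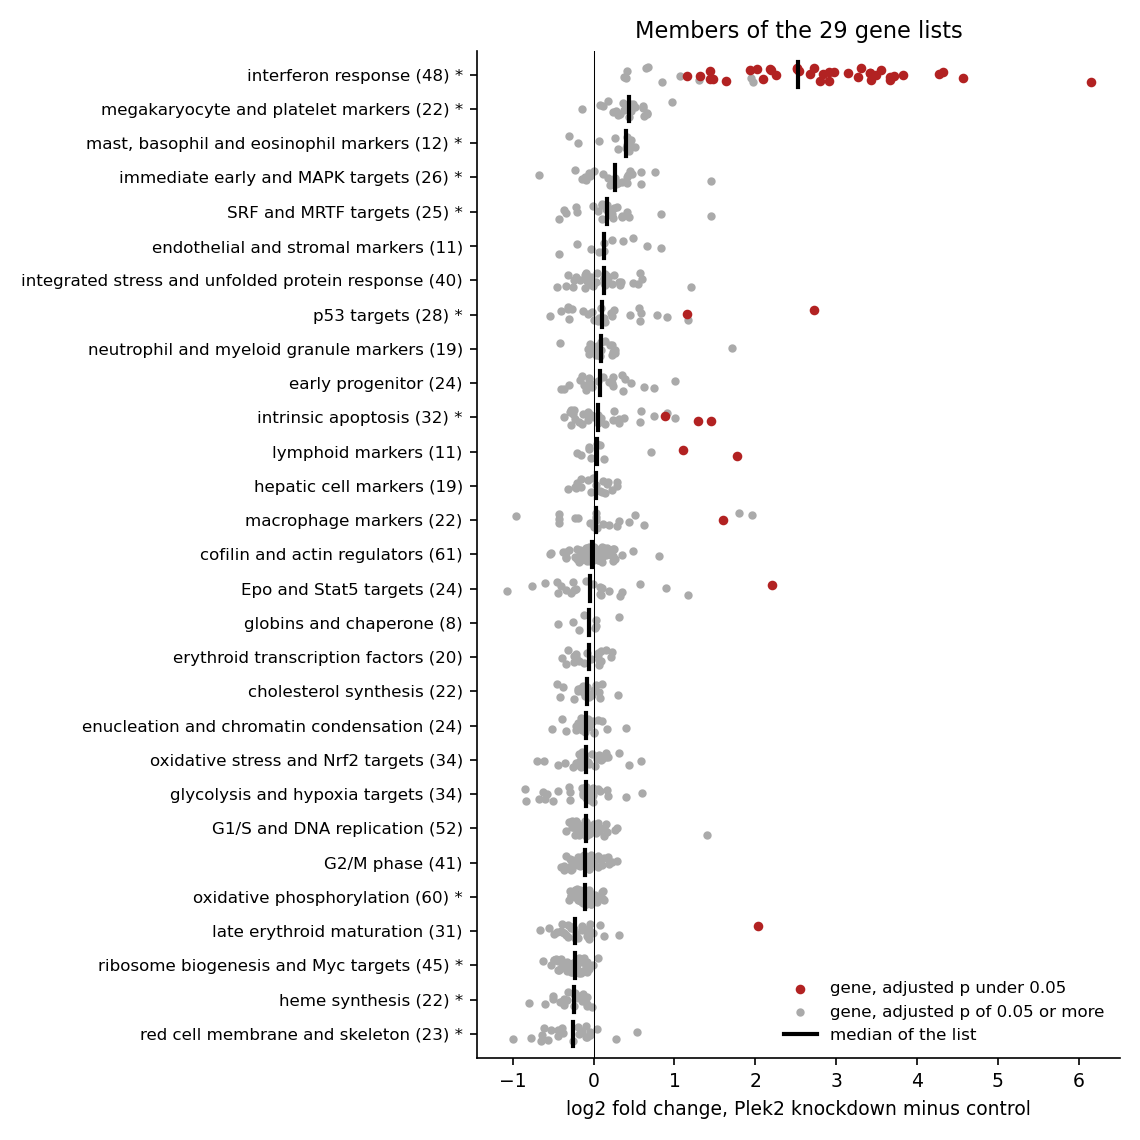
Log2 fold change (knockdown minus control) of each measured member of the 29 lists, red where the limma adjusted p is under 0.05 and grey otherwise, with black bars for list medians, the number of members in brackets and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The interferon response list has a median of 2.53, and the other medians lie between -0.25 and 0.43.

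Lists of the erythroid program shifted little, and downward where a shift was called. Heme synthesis genes had a median of -0.24, with all 22 members negative (camera adjusted p = 0.00117). No member fell on its own; Isca1, an iron-sulfur cluster protein, stood at -0.51 (SE 0.184), and Alad, the enzyme of the pathway's porphobilinogen step, at -0.36 (SE 0.168). The red cell membrane and skeleton list had a median of -0.25, with 20 of 23 members negative (adjusted p = 0.0326) and none called; Icam4 stood at -0.64 (SE 0.198) and Tmod1, which caps actin filaments, at -0.62 (SE 0.194). Neither call held with an estimated correlation (adjusted p = 0.598 and 0.606). With the replicate block 2 heme synthesis genes fell, and 1 membrane gene rose and 4 fell. The membrane list's call was lost without control replicate 1 (adjusted p = 0.391) and without knockdown replicate 3 (adjusted p = 0.108).

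Late erythroid maturation genes had a median of -0.23 without passing (adjusted p = 0.0721, 0.0219 with the replicate block, and 0.597 with the block and an estimated correlation). Its only called member went the other way: Ube2l6, a ubiquitin-conjugating enzyme that also attaches Isg15, rose by 2.04 (SE 0.24, limma adjusted p = 0.00953). With the block 1 member rose and 1 fell. Globins and their chaperone had 0 of 8 members called and a median of -0.05 (adjusted p = 0.981), although the camera test pointed up and fry down; Hbb-y stood at 0.32 (SE 0.211) and the chaperone Eraf (Ahsp) at -0.18 (SE 0.16). Erythroid transcription factors had 0 of 20 called and a median of -0.06 (adjusted p = 0.544), with Klf1 at -0.39 (SE 0.182) and Tal1 at -0.32 (SE 0.155). The enucleation and chromatin condensation list had 0 of 24 called and a median of -0.09 (adjusted p = 0.521). With the replicate block 1 of its members fell. Early progenitor genes had a median of 0.08 and did not pass (adjusted p = 0.0527, 0.0265 with the replicate block, and 0.597 with the block and an estimated correlation). Ly6a, known as Sca-1, stood at 1.01 (SE 0.188), past the threshold only with the block (adjusted p = 0.00806) and when adjusted over the list alone.

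Of the lists tied to survival and signalling, those that passed owed their called members to few genes. The intrinsic apoptosis list passed (camera adjusted p = 0.0177, and 0.418 with an estimated correlation) with a median of 0.05. It also moved up on balance by fry (adjusted p = 0.0183, and 0.158 with the replicate block). Here 3 of 32 members rose, and 4 when adjusted over the list alone, or 5 with the replicate block. The first 3 were Bcl2a1d (1.46, SE 0.17) and Bcl2a1b (1.29, SE 0.212), which encode anti-apoptotic proteins, and Casp8 (0.88, SE 0.14), the initiator caspase of death receptors. The call of Bcl2a1b was lost without normexp (adjusted p = 0.0536) and without the filter on dim probes (0.112), and that of Casp8 with median scaling (0.122). The p53 target list passed (adjusted p = 0.0035, and 0.507 with an estimated correlation) with a median of 0.11 and 2 of 28 members up (3 when adjusted over the list alone), namely Tap1 (2.73, SE 0.236), the peptide transporter of antigen presentation, which is also on the interferon list, and the kinase Plk2 (1.16, SE 0.18). Plk2 stood at 0.49 without normexp, where its call was lost (adjusted p = 0.0756), as it was with median scaling (0.101) and without the filter on dim probes (0.0756). Cdkn1a, the cell cycle inhibitor p21, stood at 1.17 (SE 0.259) with an adjusted p of 0.119, and 0.00363 with the replicate block. Immediate early and MAPK targets (median 0.27, adjusted p = 0.0177) and SRF and MRTF targets (median 0.17, adjusted p = 0.0219) passed with 0 of 26 and 0 of 25 members called, and neither held with an estimated correlation (adjusted p = 0.606 for both). With the block 4 immediate early genes rose and 1 fell, and 2 SRF targets rose and 1 fell; Egr3, on both lists, stood at 1.45 (SE 0.74), past the threshold only with the block (adjusted p = 0.00371). Both of these calls were also lost without control replicate 2 (adjusted p = 0.127 and 0.123) and without knockdown replicate 1 (0.0608 and 0.0858), and the SRF call without knockdown replicate 3 (0.148).

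Epo and Stat5 targets did not pass as a list by camera (median -0.05, mean 0.04, adjusted p = 0.791). They passed the mixed test of fry, which counts changes in either direction (adjusted p = 0.00361). The list had 1 of 24 members up, Serpina3g (2.21, SE 0.303, limma adjusted p = 0.018, and 0.0849 without the filter on dim probes), a protease inhibitor. When adjusted over the list alone 3 rose and 3 fell. With the replicate block 3 rose and 4 fell, among them Ccnd2, a D-type cyclin, at 1.17 (adjusted p = 0.00604) and Erfe, the erythroblast hormone that lowers hepcidin, at -1.08 (adjusted p = 0.0105). The cofilin and actin regulator list, chosen because pleckstrin-2 is known to act with cofilin, had 0 of 61 members called and a median of -0.01 (adjusted p = 0.567). Cofilin-1 (Cfl1) stood at -0.34 (SE 0.155), and with the block Evl rose by 0.81 (adjusted p = 0.00542) and Pdxp, the cofilin phosphatase chronophin, fell by 0.53 (adjusted p = 0.0308).

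Among general programs, ribosome biogenesis and Myc targets were lower, with a median of -0.23 and 44 of 45 members negative (camera adjusted p = 0.000451). No member fell on its own, and the call was lost with an estimated correlation (adjusted p = 0.634) and without knockdown replicate 1 (0.143); with the block 3 fell, among them Polr1b, a subunit of RNA polymerase I, at -0.63 (adjusted p = 0.0151). Oxidative phosphorylation had a median of -0.11 with 52 of 60 negative and none called (adjusted p = 0.0339, 0.689 with an estimated correlation and 0.0535 with the replicate block). This shift is close to the median of -0.06 over all probes kept, which was -0.12 under median scaling. The call was also lost without control replicate 2, control replicate 3 or knockdown replicate 1 (adjusted p = 0.127, 0.142 and 0.684). The G2/M list (median -0.10, adjusted p = 0.18), the G1/S and DNA replication list (median -0.10, adjusted p = 0.203), glycolysis and hypoxia targets (median -0.09, adjusted p = 0.0829), cholesterol synthesis (median -0.08, adjusted p = 0.166) and oxidative stress and Nrf2 targets (median -0.09, adjusted p = 0.836) did not pass and had no called members. The integrated stress and unfolded protein response list had a median of 0.13 and did not pass (adjusted p = 0.0721, 0.0209 with the block, and 0.597 with the block and an estimated correlation). Atf3, a stress-induced transcription factor, stood at 1.21 (SE 0.317, adjusted p = 0.216, and 0.00172 with the block). With the block 1 glycolysis gene rose and 4 fell, 1 cholesterol synthesis gene fell, 1 oxidative stress gene rose and 1 fell, and 2 stress response genes rose. Ccnd1, cyclin D1, the 1 member of the G1/S list to pass with the block, stood at 1.41 (SE 0.289, adjusted p = 0.0909, and 0.00196 with the block).

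Markers of other cell types shifted by different amounts. The camera test pointed up for each of these lists, and fry pointed down for the hepatic list. Their mean changes ran from 0.01 for hepatic to 0.41 for megakaryocyte markers. Megakaryocyte and platelet markers were higher, with a median of 0.43 and 21 of 22 members positive (camera adjusted p = 6.13e-05), and mast, basophil and eosinophil markers had a median of 0.41 with 10 of 12 positive (adjusted p = 0.0034). No member of either list passed on its own; Clec1b stood at 0.44 (SE 0.147) and Hdc, the histidine decarboxylase of basophils and mast cells, at 0.45 (SE 0.141). Neither call held with an estimated correlation (adjusted p = 0.606 and 0.418), and with the block 5 megakaryocyte genes rose, among them Gp1bb at 0.66 (adjusted p = 0.0154). Macrophage (median 0.03, adjusted p = 0.0721), neutrophil and myeloid granule (0.09, 0.0791), lymphoid (0.04, 0.0527), endothelial and stromal (0.13, 0.0829) and hepatic markers (0.03, 0.785) did not pass, and only the neutrophil list did with the block (adjusted p = 0.0219, and 0.597 with the block and an estimated correlation). Their called members were Fcgr1, an IgG receptor of macrophages (1.61, SE 0.147), and the lymphoid genes Lck (1.10, SE 0.147) and Cd72 (1.77, SE 0.297). Here 2 macrophage genes rose when adjusted over the list alone, and 3 with the block. The block also gave rises of 1 neutrophil and 3 lymphoid genes, and 1 rise and 1 fall among endothelial and stromal genes. The call of Cd72 was lost without normexp (adjusted p = 0.0721), with median scaling (0.138), with cyclic loess (0.0522) and without the filter on dim probes (0.149), and that of Lck with median scaling (0.0625). Replicate 1 stood apart from replicates 2 and 3 in both groups: its neutrophil markers were higher by a median of 0.93 in control and 1.20 in knockdown cultures, its macrophage markers by 0.69 and 0.79, while its hepatic markers stood at -0.66 and -0.83 and its megakaryocyte markers at -0.52 and -0.73. In total 11 lists passed with the preset correlation, 7 higher and 4 lower, against 0 with an estimated correlation, 2 by fry and 6 by its mixed test. Those passing fry were the interferon response and intrinsic apoptosis lists. The mixed test passed for both, for p53 targets, for Epo and Stat5 targets, and for macrophage and lymphoid markers (fry mixed adjusted p between 0.00299 and 0.0134). With the block 14, 0, 0 and 24 passed.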

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

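Settings that leave out a replicate pair, lists without interferon list members, probe symbols without synonyms and the estimated correlation together with the replicate block were chosen after seeing the data; the slide as a block was not run, since the slides are not given in the sources used here. The count of 318 probes stayed within 1.5 times under 11 planned settings with all arrays and moved to 1300 with the replicate block, 1746 (998 higher, 748 lower) with array weights, 165 at an adjusted p under 0.01 and 1545 at an unadjusted p under 0.05. Leaving out single arrays gave 120 to 287, lowest without control replicate 3, with 190 without control replicate 2 and 169 without knockdown replicate 3. Leaving out replicate pairs gave 306 without replicate 1, 103 without replicate 2 and, without replicate 3, 0 probes by limma, with 589 at an unadjusted p under 0.05; with the replicate block the same steps gave 629 without replicate 1, 752 without replicate 2 and 696 without replicate 3. These follow in part from fewer arrays. The fits without a replicate pair held equally many arrays, so that number alone does not account for 306 against 0 probes. With the block these counts lay closer together. Otherwise the cause was not tested. Plek2 stayed lower in every setting, at -0.75 to -1.39 log2 units, and passed with the block (-1.12, adjusted p = 0.0228), with array weights (-1.35, adjusted p = 0.00676), without knockdown replicate 2 (-1.37, adjusted p = 0.0353), and lay between -1.39 and -0.89 with arrays or pairs left out, and it passed with the block without replicate 2 (-1.39, adjusted p = 0.0116). The list count of 11 moved to 18 (9 higher, 9 lower) without the filter on dim probes, 0 with an estimated correlation, 2 by fry and 0 with an estimated correlation and the block, and lay between 11 and 13 with single arrays left out. Without members of the interferon list, 11 lists passed. This setting took only Tap1 from the measured members of the p53 target list and none from the others. It therefore cannot show that the other calls are independent of the interferon response. With probe symbols not updated through synonyms 12 passed, the lymphoid list (adjusted p = 0.0388) being the 1 call that changed.

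Of 31 genes past the threshold that were followed, 17 stayed past it under all 11 planned settings with all arrays and 13 without each array; 8, 13 and 17 were lost without control replicates 1, 2 and 3, and 9, 9 and 13 without knockdown replicates 1, 2 and 3. Genes were counted under the settings that tested them. Of the 11 lists, 10 stayed past it under the planned settings other than the estimated correlation and fry, and 6 without each array. The replicate block lost 0 of these genes and added 42 of those followed that were short of it; among lists it lost oxidative phosphorylation and added late maturation, early progenitor, integrated stress and neutrophil lists, and changed no other list call. The interferon list kept its call except with an estimated correlation (adjusted p = 0.167, and 0.597 with the block) and by fry with the block (adjusted p = 0.158), with medians of 1.9 to 2.81. These 3 tests called 0 of the 29 lists, so the lost call does not mark this list as weak.

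Directions that turned were all short of the threshold, and the cause was not tested. The test of the globin list turned at medians of -0.0545 (block, array weights, fry, and estimated correlation with the block), -0.0742 (mean of all probes of a gene), and with the block -0.089 without replicate 1 and -0.0742 without replicate 2; with arrays or pairs left out its median ran from -0.111 to 0.0252. Oxidative stress turned at -0.0382 (cyclic loess) and -0.0614 (detection p under 0.01), with -0.0762 to -0.0109 when arrays or pairs were left out, and Epo and Stat5 targets at -0.048 (no filter) and -0.0813 (block without replicate 2). Hepatic markers turned at -0.189 (detection p under 0.01) and 0.0316 (fry), and cofilin regulators at -0.0148 (fry), with ranges of -0.282 to 0.338 and -0.0852 to 0.0417 over arrays or pairs left out. In the same way macrophage markers ran from -0.214 to 0.318 and neutrophil markers from -0.177 to 0.45, each lowest without knockdown replicate 1 and highest without control replicate 1, Csf3r from -0.0123 to 0.544, Cd79b from -0.409 to 0.132 and Hbq1b from -0.319 to 0.0400. Dim probes limit what can be said: the median signal of the probes kept was 2.39 to 2.72 times that of undetected probes.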

Other observations

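Lists written after the data had been seen described further groups among the called genes, and all tests of explanations below except the splits of the arrays and the test on raw signals were chosen after the result was seen. Of 22 genes of MHC class I antigen processing 13 rose (21 with the replicate block), with a median of 1.53 log2 units, among them the immunoproteasome subunits Psmb8 (1.44, SE 0.173), Psmb9 (1.93, SE 0.221) and Psmb10 (1.35, SE 0.202). Of 12 interferon-inducible GTPases 10 rose (median 3.34), among them Igtp (3.24, SE 0.329) and Irgm2 (3.13, SE 0.317). Of 26 chemokines and cytokines 12 rose (median 1.11), among them Ccl2 (3.70, SE 0.382), Tnf (2.12, SE 0.335) and Tnfsf10, known as TRAIL. The count and the median took Tnfsf10 from the probe ILMN_2487554 (3.48, SE 0.282). The array design names that probe after a clone, and it is tied to the gene only by a synonym. The Tnfsf10 probe with a RefSeq accession stood at 1.495 (SE 0.148). Of 23 nucleic acid sensors and adaptors 8 rose (16 with the block, median 0.68), among them Cgas (1.26, SE 0.14) and the exonuclease Trex1 (2.34, SE 0.231). Of 17 NF-kB targets 2 rose (7 with the block), Ccrl2 and Cd40 (3.08, SE 0.346 for the latter). Of 13 interferons and their receptors only Ifnb1 passed in the fit on the group alone, and 2 with the block; Ifna11, not detected in control cultures, stood at least 13.2-fold higher in that fit without passing (limma adjusted p = 0.192, and 0.0301 with the replicate block), and its signal in knockdown replicate 3 (11.55) was far above that in replicates 1 and 2 (7.41 and 7.28). These genes were picked because they had moved, so the counts describe the response and are no independent evidence of it. Of 241 called symbols, 39 were on the interferon list, 72 on it or on these lists and 169 on neither.

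The rise of the interferon list was weighed against technical sources. Background correction or normalization as its source is argued against by the raw signals, where the list's pair medians were 1.97, 1.57 and 2.18 log2 units, the lowest 1.57. A single deviating culture is argued against by the lowest pair median of the normalized values, 2.14. More macrophages, neutrophils or lymphoid cells in the knockdown cultures are argued against by 52 of their markers off the interferon list. Their highest pair median was 0.134 (SD of their changes 0.598). The 4 most abundant, S100a8, Mpo, Lyz1 and Lyz2, stood at 0.09, 0.04, -0.20 and -0.24. At control log2 signals of 14.2 to 14.4 these 4 were very bright and leave little room to show a rise. Mast, basophil and eosinophil markers, with a median of 0.41, were not in this set. The selection for cells without TER119 does not remove leukocytes. A response to the hairpin RNA or its vector rather than to lower Plek2 stays open and cannot be told apart from an effect of Plek2. The labels name 1 kind of Plek2 hairpin. Plek2 changed by -1.22, -0.56 and -1.77 in the pairs with interferon medians of 2.72, 2.14 and 2.90. However, the order of 3 pairs cannot give a two-sided permutation p below 0.333, and a larger dose of hairpin could give the same order. The controls also shape this order. Control replicate 2 had the highest control signal of Ddx58, Mx1, Gbp2 and Irf7 (7.53, 6.09, 9.63 and 7.72). Knockdown replicate 2 lay below knockdown replicate 1 for Mx1 and Irf7 but not for Ddx58 and Gbp2. For these genes the smaller change in pair 2 thus came at least in part from its control.

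A second pattern was the lower heme and red cell membrane lists with higher megakaryocyte markers, whose calls did not hold with an estimated correlation. A lower share of erythroid cells as a whole would raise markers of all other types alike. The megakaryocyte minus hepatic medians were 0.312, 0.299 and 0.482 in the pairs (mean 0.365, SD 0.102). This comparison cannot decide it, since the hepatic markers were dim, with a median control level of 6.29 on the log2 scale. Mast, basophil and eosinophil markers also had a median of 0.41, against 0.03 to 0.13 for the remaining lists of other cell types. This explanation and a change in the megakaryocyte lineage itself stay open. Slower maturation of the erythroblasts may contribute and was not decided: the late maturation list had pair medians of -0.28, -0.12 and -0.29, but the early progenitor list had 0.17, -0.06 and 0.06, with a median of 0.0567. An effect of lower Plek2 was not tested apart from these.

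With 3 arrays against 3, only 10 splits exist, so no share under 0.05 can be reached. The labelled split gave 318 probes and was the only 1 of 10 with as many; the highest other split gave 272, and it set both replicate 1 arrays and knockdown replicate 3 against the others. The 3 other splits that keep both replicate 1 arrays together gave 0 probes each, and the source of the 272 was not tested. With the replicate block, the labelled split was the only 1 of the 4 that part all 3 pairs to give as many as its 1300 probes, and the highest other gave 0. For the list count in the fit on the group alone, 2 of 10 splits reached 11 lists, the highest other also giving 11. The number of called lists by itself thus did not set the labelled split apart in that fit. Camera with the preset correlation also called the interferon list in every other split (adjusted p between 9.58e-25 and 0.00393). Its median size was 0.629 to 1.11 there, against 2.53 in the labelled split. Those splits mix the groups unevenly, so part of the labelled difference remains in them. The call of this list by itself thus does not set the labelled split apart, while its size was largest there. With the block the labelled split gave 14 lists, and lists were not counted with the block for the other splits.

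Replicate 1 of both groups also differed from replicates 2 and 3 in single genes: the first principal component, with 51.6% of the variance, was -45.2 and -55.7 for the replicate 1 arrays and between 6.58 and 37.2 for the other 4. In replicate 1 the granulocyte gene Cd177 was higher by 3.61 in control and 4.01 in knockdown cultures on the probe ILMN_2789900 and by 2.29 and 2.77 on ILMN_1225233, and the hepatic gene Ambp stood at -3.84 and -4.17.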
